A study of Homo sapiens with 9 samples.

How the data were processed

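The measurements were messenger RNA levels in Caco-2 cells of the TC7 clone, a human colon adenocarcinoma line that takes on features of absorptive enterocytes. Cells had been kept at passages 50 to 60 in medium with 20% fetal calf serum. They were exposed for 24 h to 10 µM hydroxytyrosol (HTy), to 10 µM hydroxytyrosyl ethyl ether (HTy-Et) or to neither. The test solutions held 0.1% DMSO in medium without serum, and the labels do not state whether control cells received the same vehicle and medium. The series text gives 3 biological replicates of each of the 3 groups, and each was run on its own Affymetrix HG-U133 Plus 2.0 array, 9 arrays in all. Every array was placed in its group by its sample title. No batch or date is named.

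The deposited values were intensities on a linear scale, 1 value for each of 54675 probe sets per array, running from 1 to 28693.32. How the authors made these values, and whether they normalized them, is not named in the labels. Array medians lay between 125.8 and 134.2, a range of 0.094 on the log2 scale. Array distributions were therefore used without further normalization, under a limit of 0.1 log2 for the range of medians that was set after the values were seen. Values under 16, which were 2.03 to 2.23% of the probe sets of an array, were set to 16, and all were put on the log2 scale. For arrays, the number per group limits the precision of each value.

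Of the probe sets, 62 were array controls and stayed out, 41091 named 1 gene, 1801 named several genes and 11721 were unnamed here. Symbols came from Entrez identifiers through a gene table of the GRCh38.p14 assembly, used for names only, so no positions are given. That table held the identifiers of 41037 of the 1-gene probe sets and lacked 54. Each of the 19775 genes was represented by its probe set with the highest mean log2 value over the 9 arrays, which mattered for the 10523 genes with more than 1 probe set. Probe sets naming several genes or none stayed out of the gene test and were counted separately.

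Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package, version 1.17.8, for the tables. A single model held the means of the 3 groups and shared 1 spread over all 9 arrays. The 3 comparisons were HTy minus control, HTy-Et minus control and HTy-Et minus HTy, and p-values were adjusted over all genes by the Benjamini-Hochberg method within each comparison. A gene was called changed at an adjusted p under 0.05. All adjusted p-values of genes are from limma, all log2 differences are of group means, and errors after ± are standard errors unless SD is stated. Intervals are at the 95% level and are not adjusted for the number of genes.

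The 34 gene lists, covering pathways and cell type markers, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera from limma, which asks whether the genes of a list move more than other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. All adjusted p-values of lists are from camera. The same test with a correlation estimated for each list was run beside it. That setting can raise p without positive correlation. For AhR targets the estimated correlation was -0.022, yet the camera p between the compounds rose from 0.000151 to 0.00779. A call lost under it therefore need not mean that the members are correlated. The directional test of fry asks whether the genes of a list move, on balance, in 1 direction, and its mixed test whether they change in either direction. Neither compares a list with other genes. For each list, the count of changed members was taken over all genes and also adjusted over the list alone. At least 5 measured members were required.

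Named genes followed 1 rule for each comparison. Among genes past the threshold whose values did not overlap between the groups, up to 12 with the largest rise and up to 12 with the largest fall were named. Of each list described, up to 4 members with the smallest p were named, with values where they did not pass. ACTB and GAPDH were added as housekeeping references. Genes named for one comparison could be named in the others. The rule also provided for comparisons with few changed genes, which did not occur.

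The responses to the compounds share the same 3 control arrays, which alone makes them alike. Their correlation across genes, their covariance and the overlap of calls were therefore set beside 100 simulations of unchanged groups with shared controls. Each gene was drawn independently in them. RNA quality was compared as the log2 difference of 3' and 5' control probe sets of GAPDH and ACTB, with exact two-sided permutation tests. The model was tested on simulated data with 200 changed genes among 19775, in 5 runs. It recovered 57% of the genes changed 1.25-fold, 97% of those changed 1.5-fold and 100% of those changed 2-fold, and 5.5% of the calls were false. The changed genes were not drawn from the dimmest genes, so these rates do not apply to genes near the floor. Of 100 unchanged gene sets per run, 3% had p under 0.05, and a set of 20 genes shifted by 0.15 log2 was found in 5 of 5 runs. Genes were independent in these runs, so the 3% does not cover lists with correlated members. The estimated correlation was 0.468 for metallothioneins and 0.522 for ribosome biogenesis.

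The alternatives tried were median centring, quantile normalization, a floor of 32, leaving out dim genes, the mean of all probe sets of a gene, every probe set tested on its own, an intensity trend in eBayes, the replicate number as a block, only the 6 arrays of the groups compared, a change of at least 1.5-fold, the other list tests, and leaving out each array in turn. The closing section gives their effect. A further 8 gene lists were chosen after the largest changes had been seen, and they are reported only there, with p-values adjusted over all 42 lists together.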

Results

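Messenger RNA levels were measured on 9 arrays, 3 of control Caco-2/TC7 cells, 3 of cells given hydroxytyrosol (HTy) and 3 of cells given hydroxytyrosyl ethyl ether (HTy-Et). Hydroxytyrosol is a catechol phenol of olives, and HTy-Et carries an ethyl ether on its side-chain alcohol. Both were given at 10 µM for 24 h, so dose and time were matched. Values are deposited linear intensities, with n = 3 arrays per group, analysed as log2 values above a floor of 16. Whether the control cells received the DMSO vehicle, or the medium without serum of the test solutions, is not stated in the labels, so a comparison with the control may also hold an effect of the vehicle or of serum.

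The correlation between arrays of the same group, across genes, was 0.9973 to 0.998 in the control, 0.9972 to 0.998 with HTy and 0.9961 to 0.9978 with HTy-Et. It was 0.9939 to 0.9956 between control and HTy-Et arrays, 0.9956 to 0.9972 between control and HTy arrays and 0.995 to 0.9972 between the compounds. Genes are not independent replicates in these values. The first principal component held 32.3% of the variance and placed the control at -12.5 ± 0.5 (SD), HTy at 0.4 ± 1.1 (SD) and HTy-Et at 12.1 ± 2.3 (SD). The second held 21.2% and spread arrays within groups: 10.48, 0.72 and 1.60 for the control replicates 1 to 3, -1.77, -13.54 and -9.14 for HTy and 4.23, -5.72 and 13.15 for HTy-Et. On the third, HTy-Et replicate 3 stood at -9.85, apart from HTy-Et replicates 1 and 2 at 10.40 and 7.75. The 3' minus 5' log2 signal of the GAPDH control probe sets was 0.055 ± 0.015 (SD) in the control, 0.046 ± 0.008 (SD) with HTy and 0.048 ± 0.005 (SD) with HTy-Et. For the ACTB control probe sets it was 0.233 ± 0.012 (SD), 0.26 ± 0.046 (SD) and 0.24 ± 0.027 (SD). Exact two-sided permutation tests of these values between pairs of groups gave p from 0.4 to 0.8, where 0.10 is the smallest p that 3 arrays against 3 allow. The housekeeping gene ACTB differed by -0.03 log2 with HTy (adjusted p = 0.721) and by -0.07 with HTy-Et (adjusted p = 0.185). GAPDH, whose intensity lies near the top of the scale, differed by 0.08 (adjusted p = 0.193) and 0.10 (adjusted p = 0.0736).

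The comparison of HTy with the control asked which transcripts differ in cells exposed to hydroxytyrosol. Metallothionein genes, which code for small proteins that bind zinc and copper, rose the most. MT2A went from an intensity of 1326 ± 90.91 (SD) in the control to 5491 ± 197.2 (SD), which is 4.15-fold, a log2 rise of 2.05 ± 0.06 (adjusted p = 4.26e-06). Of the measured genes that respond to low oxygen, 16 of 20 also rose, as did 11 of 17 genes of glycolysis and 20 of 25 genes of the ATF4 pathway, which answers amino acid shortage and other stresses, while 7 of 26 mitosis genes fell. Of these lists, ATF4 alone stayed called with an estimated correlation (adjusted p = 0.00516, against 0.0627 for hypoxia and for glycolysis and 0.116 for mitosis). Of 19775 genes, 453 (2.3%) changed, 349 up and 104 down, and the median size of their change was 0.31 log2.

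Other metallothionein genes rose by similar amounts in HTy cells: MT1X by 2.04 ± 0.09 (adjusted p = 2.99e-05), MT1H by 2.00 (adjusted p = 1.26e-05), MT1HL1 by 2.00 (adjusted p = 8.04e-06) and MT1F by 1.94 ± 0.07 (adjusted p = 1.26e-05). MT1G rose by 0.86 ± 0.07 (adjusted p = 0.000805). In the list of metallothioneins and the zinc exporter SLC30A1, 5 of 8 measured members (of 9) rose, and 8 did when adjusted over the list alone. The list median was 1.40 and camera gave an adjusted p = 1.96e-14, which was an adjusted p = 0.0627 with an estimated correlation. SLC30A1 differed by 0.26 ± 0.10 (adjusted p = 0.202). Metallothionein probe sets are not independent readings, because 10 of the 12 are of a type that can bind several related transcripts. Among those 10, 9 were higher with HTy, 8 of them by 1.94 to 2.26 log2. Neither of the 2 gene-specific sets passed, with control intensities of 36.1 and 83.3.

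Outside the metallothioneins, the largest rises with HTy were in SPAG4, by 1.56 ± 0.11 (adjusted p = 0.000484), and DDIT4, an inhibitor of mTORC1 signalling, by 1.33 ± 0.05 (adjusted p = 1.38e-05). The ubiquitin ligase gene RNF183 rose by 1.19 (adjusted p = 0.00153), BNIP3, which acts in mitophagy, by 1.14 ± 0.09, and BHLHE40, a transcriptional repressor tied to the circadian clock, by 1.09 (adjusted p = 0.000734). TMCC1 rose by 1.19 (adjusted p = 1.26e-05) and RIMKLA by 1.09 (adjusted p = 0.00603). The 7 probe sets of TMCC1 ranged from -0.11 up to the value given and the 2 sets of BHLHE40 from 0.04 to 1.09, and those of RIMKLA also disagreed, so these values hold for the probe set used. The largest fall was in SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis, by -0.65 ± 0.10 (adjusted p = 0.0198). Mitotic genes among the largest falls were KIF23 at -0.45 (adjusted p = 0.0136), PIMREG at -0.43 (adjusted p = 0.0102), CDC20, an activator of the anaphase-promoting complex, at -0.40 ± 0.05 (adjusted p = 0.00563), CCNF at -0.40 (adjusted p = 0.0232), CENPE at -0.37 (adjusted p = 0.0354) and CENPA, the histone of centromeres, at -0.37 ± 0.03 (adjusted p = 0.00201). Other large falls were GTF2H2B at -0.47, KBTBD8 at -0.44, STK24-AS1 at -0.41, the antimicrobial peptide gene DEFB1 at -0.38 and LPCAT1 at -0.36. Each gene named here as the largest had no overlap between the values of the groups, which held for 28.7% of all genes, where chance gives 10%. With 1 array left out, 9 of these 24 calls ended (SPTSSB, GTF2H2B, KIF23, STK24-AS1, CCNF, CENPE, PIMREG, LPCAT1 and DEFB1), and the highest adjusted p among them was 0.157. The RIMKLA call ended with the mean of its probe sets, at an adjusted p = 0.0524, and those of GTF2H2B and STK24-AS1 with that mean and with only the 6 arrays compared.

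In the ATF4 and amino acid response list, 20 of 25 measured members (of 26) rose with HTy, 22 when adjusted over the list alone, with a median of 0.36 (adjusted p = 1.59e-22, and adjusted p = 0.00516 with an estimated correlation). Examples are STC2, a secreted glycoprotein, at 0.91, the cystine transporter SLC7A11 at 0.91 ± 0.07 (adjusted p = 0.000947), and the transcription factor CEBPB at 0.44. In the hypoxia response list, 16 of 20 measured members (of 21) rose, 17 when adjusted over the list alone, with a median of 0.54 (adjusted p = 1.08e-21, and adjusted p = 0.0627 with an estimated correlation). PFKFB4, which controls glycolytic flux, rose by 1.04 (adjusted p = 0.000227). PDK1, which inhibits pyruvate dehydrogenase, rose by 0.89, the collagen prolyl hydroxylase gene P4HA1 by 0.71 and INSIG2 by 0.70 (adjusted p = 7.52e-05). In the glycolysis list, 11 of 17 measured members (of 18) rose, 15 when adjusted over the list alone, with a median of 0.25 (adjusted p = 1.13e-13, and adjusted p = 0.0627 with an estimated correlation). ALDOC rose by 0.96, HK1 by 0.40, HK2 by 0.38 and ALDOA by 0.27.

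Cell-cycle lists moved in opposite directions. Of the 26 mitosis genes, all measured, 7 fell and 0 rose, and 15 fell and 1 rose when adjusted over the list alone, with a median of -0.15 (adjusted p = 1.18e-14, and adjusted p = 0.116 with an estimated correlation). Of 15 measured cell-cycle inhibitors (of 17), 3 rose, 5 when adjusted over the list alone, with a median of 0.13 (adjusted p = 4.22e-05, and adjusted p = 0.22 with an estimated correlation). These were CCNG2 at 0.85, CDKN1A, which codes for the inhibitor p21, at 0.57 (adjusted p = 0.000887) and BTG1 at 0.53. The G1/S and DNA replication list was not called: 1 of 28 measured members (of 29), the licensing factor CDT1, rose, by 0.24, also 1 when adjusted over the list alone (adjusted p = 0.606).

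Among other lists, 6 of 24 measured NRF2 targets (of 26) rose, 11 when adjusted over the list alone, with a median of 0.12 (adjusted p = 7.43e-06, and adjusted p = 0.271 with an estimated correlation), among them AKR1C3 at 0.45, the export pump ABCC2 at 0.43 and PIR at 0.26. Of 17 measured immediate early genes (of 18), 6 rose, 9 when adjusted over the list alone, with a median of 0.24 (adjusted p = 1.5e-07, and adjusted p = 0.152 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 0.84 ± 0.08 (adjusted p = 0.00186), KLF6 by 0.37, JUND by 0.36 and MYC by 0.27. No heat shock gene passed among 10 measured (of 13), 3 fell when adjusted over the list alone, and all 10 values were negative, with a median of -0.10 (adjusted p = 7.92e-05, and adjusted p = 0.134 with an estimated correlation). DNAJB1 stood at -0.36 (adjusted p = 0.0511). No ribosome biogenesis gene passed among 15 measured (of 19), 2 fell when adjusted over the list alone, and the median was -0.06 (adjusted p = 0.00069, and adjusted p = 0.39 with an estimated correlation). Of 21 measured NF-kB and inflammatory genes (of 22), the chemokine gene CCL20 rose, by 0.43, while 9 rose and 1 fell when adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0177, and adjusted p = 0.271 with an estimated correlation). Of 17 measured pro-apoptotic genes (of 20), 3 rose, 5 when adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0334, and adjusted p = 0.152 with an estimated correlation). Those 3 were BNIP3, BNIP3L at 0.78, which like BNIP3 acts in mitophagy, and PDCD4 at 0.66, an inhibitor of translation. Of 14 measured xenobiotic transporters and CYP3A genes (of 20), 3 rose, 4 when adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0493, and adjusted p = 0.24 with an estimated correlation). They were ABCC2, SLCO2B1 at 0.27 and ABCC1 at 0.26. The medians of this list and of ribosome biogenesis depended on the scaling of the arrays, at 0.03 and -0.10 after median centring. The call of the transporter list ended without control replicate 1, control replicate 3 or HTy replicate 1, with adjusted p up to 0.185, and also with quantile normalization, with the mean of all probe sets and without dim genes. The pro-apoptotic call ended without dim genes, at an adjusted p = 0.11, and without control replicate 2, HTy replicate 1 or HTy replicate 3, with adjusted p up to 0.0548, and the NF-kB call without control replicate 2, at 0.0808.

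The other 21 lists were not called for HTy, with adjusted p from 0.0621 to 0.973. Among AhR targets, 2 of 8 measured (of 8) rose, 4 when adjusted over the list alone, including CYP1A1, an enzyme that oxidises aromatic compounds, at 0.81 ± 0.11 (adjusted p = 0.0102). Among p53 targets, 4 of 18 measured (of 20) rose and 1 fell, with 5 and 1 when adjusted over the list alone. The ER chaperone list also holds genes that do not code for chaperones, such as HERPUD1 and EDEM1. In it, 1 of 18 (of 18) rose, HERPUD1 at 0.41, and 1 fell, SDF2L1 at -0.22, with 3 and 1 when adjusted over the list alone. In lipid metabolism, 1 of 19 measured cholesterol genes (of 25) rose, INSIG1 at 0.33, also 1 when adjusted over the list alone. Of 14 fatty acid synthesis genes (of 16), 1 rose, ACSL5 at 0.31, and 4 rose and 2 fell when adjusted over the list alone. Of 20 fatty acid oxidation and PPAR genes (of 22), 2 rose, PLIN2, a coat protein of lipid droplets, at 0.63 and CPT1A at 0.35, with 3 up and 1 down when adjusted over the list alone. Of 16 Wnt targets (of 18), 2 rose, MYC and SOX9 at 0.27, and 3 when adjusted over the list alone. Of 10 anti-apoptotic genes (of 11), 1 rose, BCL2L2 at 0.24, with 1 up and 2 down when adjusted over the list alone. No member passed over all genes in 21 antioxidant enzymes (of 22), 23 lipid absorption genes (of 23), 10 iron genes (of 12), 18 interferon genes (of 19), 23 enterocyte genes (of 24), 14 fibroblast genes (of 14) and 10 leukocyte genes (of 13). When adjusted over the list alone, 1, 1, 1, 2, 2 and 2 rose in the first 6 of these and 1 fell in the leukocyte list. No member passed either way in 27 conjugating enzymes (of 32), 27 oxidative phosphorylation genes (of 31), 10 goblet cell genes (of 10), 9 enteroendocrine genes (of 10) and 9 Paneth and stem cell genes (of 10).

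For HTy against control, the limma count of 453 rested on all arrays: it was 180, 123 and 197 without control replicate 1, 2 or 3, and 204, 123 and 114 without HTy replicate 1, 2 or 3. The share of changed genes that were higher, 77%, was 61.8% with quantile normalization (315 of 510) and 66.9% with median centring (190 of 284).

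The comparison of HTy-Et with the control asked the same of the ethyl ether. In the ATF4 list 23 of 25 measured genes rose, in the hypoxia list 17 of 20 and in the glycolysis list 12 of 17, of which the ATF4 list alone stayed called with an estimated correlation (adjusted p = 0.00312, against 0.101 for each of the others). CYP1A1 was among the largest rises, but the metallothionein genes did not pass. SPAG4 rose 3.54-fold, by 1.83 (adjusted p = 6.51e-05), CYP1A1 rose 3.15-fold, from 875.5 ± 11.54 (SD) to 2782 ± 467.4 (SD), by 1.65 (adjusted p = 9.03e-05), and DDIT4 rose 3.09-fold, by 1.63 (adjusted p = 7.93e-06). Of 19775 genes, 2997 (15.2%) changed, 1909 up and 1088 down, with a median size of 0.27 log2. Of these, 203 changed at least 1.5-fold, 188 up and 15 down.

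Further large rises with HTy-Et were in ATF3 at 1.57 (adjusted p = 3.12e-05), SLC7A11 at 1.53 (adjusted p = 3.12e-05), GDF15, a stress-induced secreted factor, at 1.52 (adjusted p = 7.93e-06), the calcium-binding protein gene S100P at 1.38 (adjusted p = 0.000309), EMP1 at 1.31 (adjusted p = 3.82e-05) and MAFF, a small Maf transcription factor, at 1.29 (adjusted p = 7.98e-05). TMCC1 rose by 1.27, RNF183 by 1.26 (adjusted p = 0.000256) and BHLHE40 by 1.26 (adjusted p = 9.03e-05). Probe sets ranged from 0.10 to 1.57 for ATF3 and from 0.01 to 1.52 for GDF15, and the 6 sets of EMP1 also disagreed. The largest falls were SPTSSB at -0.97 (adjusted p = 0.000762), CYMP at -0.79 (adjusted p = 0.00227), HSPA2 at -0.78 (adjusted p = 0.0198), HNRNPD-DT at -0.72 (adjusted p = 0.00238), ATF7IP2 at -0.66 (adjusted p = 0.00159), the DNA helicase gene PIF1 at -0.64 (adjusted p = 0.00494) and HPDL at -0.63 (adjusted p = 0.000445). They were followed by MATR3 at -0.62 (adjusted p = 0.00922), WWTR1, which codes for the coactivator TAZ, at -0.62 (adjusted p = 0.0178), DLEU2 at -0.61 (adjusted p = 0.000256), POLR3G at -0.60 (adjusted p = 0.00318) and SCFD2 at -0.60 (adjusted p = 0.000506). None of these genes overlapped between groups, which held for 31.8% of all genes, where chance gives 10%. The HSPA2 call ended without HTy-Et replicate 1 or 2, with adjusted p up to 0.0649. With only the 6 arrays compared, HSPA2 and WWTR1 no longer passed, at 0.0516 and 0.0553, and with the mean of all probe sets DLEU2 did not, at 0.116.

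In the ATF4 list, 23 of 25 measured members rose with HTy-Et, also 23 when adjusted over the list alone, with a median of 0.66 (adjusted p = 6.67e-27, and adjusted p = 0.00312 with an estimated correlation). The asparagine synthetase gene ASNS rose by 0.96 (adjusted p = 2.82e-05), STC2 by 1.13 and CEBPB by 0.79. In the hypoxia list, 17 of 20 rose, also 17 when adjusted over the list alone, with a median of 0.72 (adjusted p = 1.45e-16, and adjusted p = 0.101 with an estimated correlation). PFKFB4 rose by 0.96 (adjusted p = 9.03e-05), PDK1 and VEGFA, the angiogenic growth factor, by 0.91 each and P4HA1 by 0.86. In the glycolysis list, 12 of 17 rose, 15 when adjusted over the list alone, with a median of 0.28 (adjusted p = 1.69e-10, and adjusted p = 0.101 with an estimated correlation). ALDOC rose by 1.13, HK2 by 0.51, GPI by 0.35 and ALDOA by 0.34. Of the metallothionein list, 1 of 8 rose, SLC30A1 at 0.43 (adjusted p = 0.0188), also 1 when adjusted over the list alone, and the list was not called (median -0.05, adjusted p = 0.59). The 3 probe sets of SLC30A1 ranged from -0.19 to 0.66. MT2A differed by -0.09 (adjusted p = 0.378) and MT1X by -0.23 (adjusted p = 0.155).

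With HTy-Et, 16 of 26 mitosis genes fell and 1 rose, 18 and 1 when adjusted over the list alone, with a median of -0.19 (adjusted p = 4.73e-10, and adjusted p = 0.143 with an estimated correlation). CDC20 stood at -0.55 (adjusted p = 0.000281), CENPA at -0.43 (adjusted p = 0.00021), CCNB1, the mitotic cyclin, at -0.37 and the kinase gene AURKA at -0.30. Of 15 cell-cycle inhibitors, 6 rose, 8 when adjusted over the list alone, with a median of 0.23 (adjusted p = 1.21e-05, and adjusted p = 0.158 with an estimated correlation). CCNG2 rose by 1.17, CDKN1A by 1.00 (adjusted p = 3.03e-05), BTG1 by 0.80 and GADD45A by 0.54. Of 28 G1/S genes, 1 rose, CDT1 at 0.28, and 5 fell, 1 and 6 when adjusted over the list alone, and the list was not called (adjusted p = 0.055).

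NRF2 targets rose in 15 of 24 cases, 17 when adjusted over the list alone, with a median of 0.29 (adjusted p = 3.09e-11, and adjusted p = 0.12 with an estimated correlation). GCLC, a subunit of the rate-limiting enzyme of glutathione synthesis, rose by 0.69, ABCC2 by 0.75 and PIR by 0.42. Of 8 AhR targets, 4 rose, and 4 rose and 1 fell when adjusted over the list alone, with a median of 0.24 (adjusted p = 0.00412, and adjusted p = 0.101 with an estimated correlation). They were CYP1A1, TIPARP, which limits AhR signalling, at 0.65, the glucuronidating enzyme gene UGT1A6 at 0.44 and NQO1 at 0.35. Of 14 xenobiotic transporters and CYP3A genes, 7 rose, also 7 when adjusted over the list alone, with a median of 0.17 (adjusted p = 0.000618, and adjusted p = 0.101 with an estimated correlation), including ABCC5 at 0.53 and ABCC1 at 0.33. Immediate early genes rose in 11 of 17 cases, 12 when adjusted over the list alone, with a median of 0.49 (adjusted p = 4.24e-09, and adjusted p = 0.119 with an estimated correlation). KLF6 rose by 0.86, JUND by 0.62 and MYC by 0.59.

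Of 21 NF-kB and inflammatory genes, 9 rose with HTy-Et, and 9 rose and 2 fell when adjusted over the list alone, with a median of 0.16 (adjusted p = 0.00508, and adjusted p = 0.221 with an estimated correlation). They include PTGS2, the inducible cyclooxygenase, at 0.85, the inhibitors TNFAIP3 and NFKBIA at 0.59 each and the adhesion molecule ICAM1 at 0.47. Of 18 genes of the ER chaperone list, 6 rose and 2 fell, 10 and 2 when adjusted over the list alone, with a median of 0.10 (adjusted p = 0.00508, and adjusted p = 0.295 with an estimated correlation). HERPUD1 rose by 0.75, DNAJB9 by 0.69 and EDEM1 by 0.40. Of 10 heat shock genes, 5 fell, 7 when adjusted over the list alone, with a median of -0.21 (adjusted p = 2.08e-05, and adjusted p = 0.101 with an estimated correlation), including DNAJB1 at -0.50, HSPH1 at -0.33 and DNAJA1 at -0.28. Of 15 ribosome biogenesis genes, 3 fell, 6 when adjusted over the list alone, with a median of -0.14 (adjusted p = 0.000618, and adjusted p = 0.389 with an estimated correlation). They were RRP9 at -0.46, POLR1A at -0.24 and MYBBP1A at -0.22. Of 23 enterocyte genes, 7 rose, also 7 when adjusted over the list alone, with a median of 0.09 (adjusted p = 0.00508, and adjusted p = 0.158 with an estimated correlation), among them the peptide transporter SLC15A1 at 0.55 (adjusted p = 0.00141), CEACAM1 at 0.52, the brush border peptidase DPP4 at 0.43 and the intestinal transcription factor CDX2 at 0.37.

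The other 20 lists were not called for HTy-Et, with adjusted p from 0.055 to 0.916. Besides the metallothionein and G1/S lists, members changed in the p53 list (5 up and 2 down, 5 and 3 when adjusted over the list alone), the pro-apoptotic list (6 and 2, also 6 and 2), the anti-apoptotic list (2 and 1, then 4 and 2) and the fatty acid synthesis list (4 and 2, then 5 and 3). BNIP3L rose by 1.00 and PMAIP1, a BCL2-family cell death gene, by 0.62, while BAX stood at -0.30. Members also changed among fatty acid oxidation and PPAR genes (4 up and 1 down, then 5 and 1), conjugating enzymes (2 and 2, then 1 and 2), cholesterol genes (1 and 1, also 1 and 1) and iron genes (2 and 1, also 2 and 1). PLIN2 rose by 0.82, CPT1A by 0.68 and the haem-degrading enzyme gene HMOX1 by 0.63 (adjusted p = 0.00464), while UGT2A3 stood at -0.52. Of antioxidant enzymes 3 rose, also 3 when adjusted over the list alone, including TXNRD1 at 0.45 and GLRX at 0.36. Of Wnt targets 3 rose, also 3, and of interferon genes 1 rose, IRF1 at 0.50, and 2 fell, IFIT1 at -0.54 and IFI6 at -0.33, the same counts when adjusted over the list alone. Of lipid absorption genes 1 rose and 1 fell, and 0 when adjusted over the list alone. Among markers of other cell types, 1 Paneth and stem cell gene rose and 1 fell, 1 fibroblast gene rose and 2 leukocyte genes fell, the same counts when adjusted over the list alone. No oxidative phosphorylation, goblet or enteroendocrine gene passed either way.

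For HTy-Et against control, the limma count of 2997 was 1887 without control replicate 2. The share of changed genes that were higher, 63.7%, was 52.2% with quantile normalization (1634 of 3128).

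**Figure D1:**
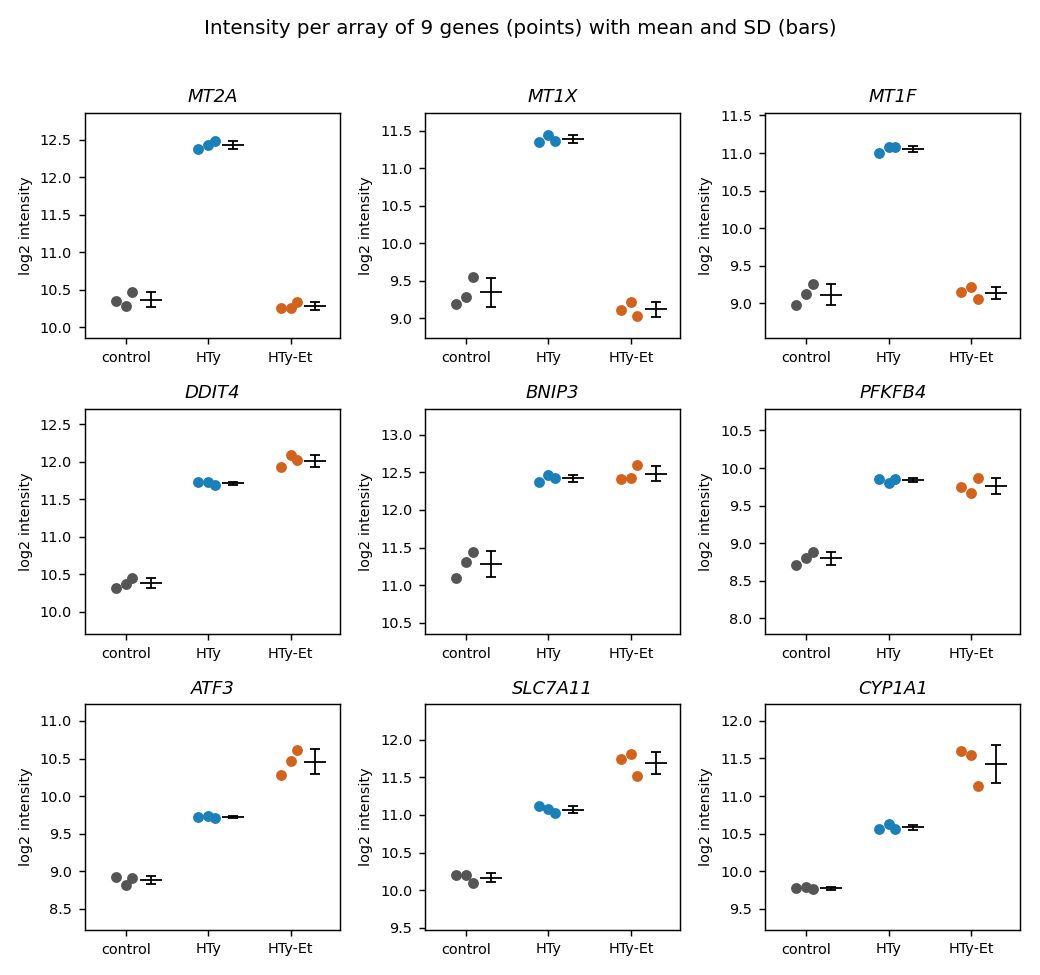
Log2 intensity of 9 genes on each of the 9 arrays, by group, with points for arrays and a bar with its whisker for the mean and SD of 3 arrays; each panel spans 3 log2 units. MT2A, MT1X and MT1F are higher with HTy alone, DDIT4, BNIP3 and PFKFB4 are higher with both compounds, and ATF3, SLC7A11 and CYP1A1 are highest with HTy-Et.

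The direct comparison of HTy-Et with HTy asked where the ethyl ether and its parent phenol differ at the same dose and time. Metallothionein genes were lower with HTy-Et: MT2A by -2.14 (95% interval -2.27 to -2.01, adjusted p = 3.02e-06) and MT1X by -2.27 (-2.48 to -2.05, adjusted p = 2.03e-05). In the ATF4 list 15 of 25 genes were higher with HTy-Et, and so were 7 of 24 NRF2 targets and 3 of 8 AhR targets, but with an estimated correlation the calls of the NRF2 and AhR lists were lost (adjusted p = 0.154 and 0.102). Single genes higher with HTy-Et were GDF15, by 0.78 (0.66 to 0.90, adjusted p = 0.000871), CYP1A1, by 0.84 (0.60 to 1.09, adjusted p = 0.0125) and ATF3, by 0.74 (0.56 to 0.91, adjusted p = 0.00661). For most hypoxia and glycolysis genes the compounds did not differ past the threshold. Of 19775 genes, 419 (2.1%) differed, 357 higher and 62 lower with HTy-Et, with a median size of 0.28 log2.

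Further genes higher with HTy-Et were S100P by 1.01 (0.73 to 1.28, adjusted p = 0.00893), MYH14 by 0.84 (0.62 to 1.05, adjusted p = 0.00781), EMP1 by 0.80 (0.65 to 0.96, adjusted p = 0.00272), CREBRF, a regulator of the unfolded protein response, by 0.75 (0.63 to 0.86, adjusted p = 0.000871) and ANKRD1 by 0.71 (0.55 to 0.87, adjusted p = 0.00477). ERN1, which codes for the stress sensor IRE1, was higher by 0.63 (0.51 to 0.76, adjusted p = 0.00272), the clock repressor NR1D2 by 0.63 (0.53 to 0.73, adjusted p = 0.000982), TXNIP, an inhibitor of thioredoxin, by 0.63 (adjusted p = 0.0252) and SLC7A11 by 0.62 (0.45 to 0.79, adjusted p = 0.00893). The metallothioneins MT1HL1 (-2.18), MT1H (-2.12), MT1F (-1.92) and MT1G (-0.88, interval -1.04 to -0.72) were lower, followed by PLAGL1 at -0.49 (adjusted p = 0.042), FAM111B at -0.47 (adjusted p = 0.0265), the fibrinogen gene FGA at -0.43 (adjusted p = 0.0294), ATP6V1C2 at -0.42 (adjusted p = 0.0261), LHFPL3-AS2 at -0.39 (adjusted p = 0.0147) and MRPL45P2 at -0.39 (adjusted p = 0.0361), which lies near the floor. Values of the groups did not overlap for any of these genes, which held for 22.9% of all genes, where chance gives 10%. Leaving out 1 array ended the calls of TXNIP, PLAGL1, FAM111B, FGA, ATP6V1C2, MRPL45P2, LHFPL3-AS2 and CYP1A1 for several choices of array, and those of S100P and SLC7A11 without HTy replicate 3, with adjusted p up to 0.156. With only the 6 arrays compared, S100P (adjusted p = 0.057), CYP1A1 (adjusted p = 0.0699), TXNIP, FAM111B, FGA, ATP6V1C2, MRPL45P2 and LHFPL3-AS2 no longer passed. The MRPL45P2 call also ended with median centring and the PLAGL1 call with quantile normalization. With the mean of all probe sets of a gene, MYH14, EMP1, GDF15, ERN1, PLAGL1, FGA and ATP6V1C2 were no longer past the threshold, with adjusted p up to 0.677.

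Among lists, the ATF4 list differed most clearly between the compounds: 15 of 25 members were higher with HTy-Et, 23 when adjusted over the list alone, with a median of 0.26 and a mean of 0.31 (0.27 to 0.34). Camera gave an adjusted p = 1.08e-25, and adjusted p = 0.00356 with an estimated correlation. CTH was higher by 0.59, ASNS by 0.51 (adjusted p = 0.00272) and CEBPB by 0.35. In the metallothionein list, 5 of 8 were lower, 7 when adjusted over the list alone, with a median of -1.40 and a mean of -1.24 (-1.40 to -1.07, adjusted p = 6.06e-13, and adjusted p = 0.102 with an estimated correlation), while SLC30A1 differed by 0.18 (-0.04 to 0.40, adjusted p = 0.38). Of 24 NRF2 targets, 7 were higher, 13 when adjusted over the list alone, with a median of 0.19 and a mean of 0.21 (0.13 to 0.30, adjusted p = 1.25e-11, and adjusted p = 0.154 with an estimated correlation), such as GCLC by 0.44 (adjusted p = 0.00789) and ABCC2 by 0.32. Of 8 AhR targets, 3 were higher, 4 when adjusted over the list alone, with a median of 0.11 and a mean of 0.22 (0.16 to 0.27, adjusted p = 0.000733, and adjusted p = 0.102 with an estimated correlation). They were CYP1A1, TIPARP by 0.51 (adjusted p = 0.0042) and NQO1 by 0.18. Of 17 immediate early genes, 6 were higher, 8 when adjusted over the list alone, with a median of 0.23 and a mean of 0.19 (0.05 to 0.34, adjusted p = 1.92e-07, and adjusted p = 0.154 with an estimated correlation), including KLF6 by 0.50 and MYC by 0.32. Of 15 cell-cycle inhibitors, 4 were higher, 5 when adjusted over the list alone, with a median of 0.10 and a mean of 0.12 (0.04 to 0.20, adjusted p = 0.000706, and adjusted p = 0.289 with an estimated correlation), including CDKN1A by 0.43 (adjusted p = 0.0067) and GADD45A by 0.33 (adjusted p = 0.0477).

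Smaller differences were called in 9 further lists. Of 18 genes of the ER chaperone list, 2 were higher with HTy-Et, 6 when adjusted over the list alone, with a median of 0.09 (adjusted p = 1.61e-05, and adjusted p = 0.154 with an estimated correlation). They were DNAJB9 by 0.42 and HERPUD1 by 0.33. Of 14 xenobiotic transporters, 3 were higher, also 3 when adjusted over the list alone, with a median of 0.07 and a mean of 0.10 (0.06 to 0.15, adjusted p = 0.00342, and adjusted p = 0.154 with an estimated correlation). Of 18 p53 targets, 4 were higher, and 4 higher and 1 lower when adjusted over the list alone, with a median of 0.03 and a mean of 0.08 (0.05 to 0.11, adjusted p = 0.0353, and adjusted p = 0.154 with an estimated correlation). Of 10 anti-apoptotic genes, 1 was higher, BCL2L2 by 0.27, also 1 when adjusted over the list alone, with a median of 0.06 (adjusted p = 0.0287, and adjusted p = 0.154 with an estimated correlation). Of 21 NF-kB genes, 1 was higher, PTGS2 by 0.56 (adjusted p = 0.0266), and 4 higher and 1 lower when adjusted over the list alone, with a median of 0.04 (adjusted p = 0.0399, and adjusted p = 0.393 with an estimated correlation). No member passed either way in the heat shock list (median -0.08, adjusted p = 0.0203, and adjusted p = 0.289 with an estimated correlation), the G1/S list (median -0.06, adjusted p = 0.022, and adjusted p = 0.399 with an estimated correlation) and the enterocyte list (median 0.03, adjusted p = 0.0353, and adjusted p = 0.289 with an estimated correlation). The list mean differed by 0.08 (-0.02 to 0.17) for NF-kB genes and by 0.07 (-0.01 to 0.14) for enterocyte genes, so both intervals held 0. The directional fry test called neither list (adjusted p = 0.15 and 0.155). After median centring the intervals were 0.01 to 0.24 and 0.04 to 0.19.

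For hypoxia genes the difference between the compounds was small. Of 20 members, 1 was higher with HTy-Et, VEGFA by 0.40 (adjusted p = 0.00477), also 1 when adjusted over the list alone. The list mean differed by 0.08 (-0.02 to 0.17) and the median by 0.06 (adjusted p = 0.0035, and adjusted p = 0.399 with an estimated correlation). Leaving out 1 array ended the calls of the hypoxia, p53, heat shock, enterocyte, anti-apoptotic, G1/S and NF-kB lists, with adjusted p up to 0.142. The p53 and anti-apoptotic calls also ended with quantile normalization and without dim genes, the enterocyte call without dim genes and the G1/S call with the mean of all probe sets. PFKFB4 differed by -0.08 and PDK1 by 0.02. Glycolysis differed by a mean of 0.04 (-0.01 to 0.09, adjusted p = 0.0879) and mitosis by -0.04 (-0.11 to 0.03, adjusted p = 0.12), with 0 members past the threshold in both, also 0 when adjusted over the list alone. These means depended on the scaling of the arrays: after median centring they were 0.09 (0.02 to 0.16) for glycolysis and 0.01 (-0.08 to 0.09) for mitosis.

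The other 17 lists were not called between the compounds, with adjusted p from 0.152 to 0.965. Of antioxidant enzymes 2 were higher with HTy-Et, also 2 when adjusted over the list alone: TXNRD1 by 0.26 and GLRX by 0.19. Of fatty acid synthesis genes, 1 was higher, ACSL5 by 0.38, and 1 lower, ELOVL6 by -0.21, the same counts when adjusted over the list alone. Of interferon genes 1 was higher, IRF1 by 0.30 (adjusted p = 0.021), of Wnt targets 1 was higher, MYC, and of Paneth and stem cell genes 1 was lower, PLA2G2A by -0.24 (adjusted p = 0.0317), with the same counts when adjusted over the list alone. No member passed over all genes in the pro-apoptotic, conjugating enzyme, cholesterol, fatty acid oxidation, lipid absorption, oxidative phosphorylation, iron, ribosome biogenesis, goblet, enteroendocrine, fibroblast and leukocyte lists. When adjusted over the list alone, 3 pro-apoptotic genes were higher and 1 lower, 1 conjugating enzyme was higher and 1 lower, 2 fatty acid oxidation genes were higher, 2 fibroblast genes were lower, and 1 leukocyte gene was higher and 2 lower.

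For HTy-Et against HTy, the limma count of 419 was 90 and 148 without HTy-Et replicate 1 or 2, and 84, 65 and 48 without HTy replicate 1, 2 or 3. With only the 6 arrays of the compounds in the model it was 86. The share of these genes that were higher with HTy-Et, 85.2%, was 81.3% with quantile normalization (270 of 332) and 94% with median centring (611 of 650).

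**Figure D2:**
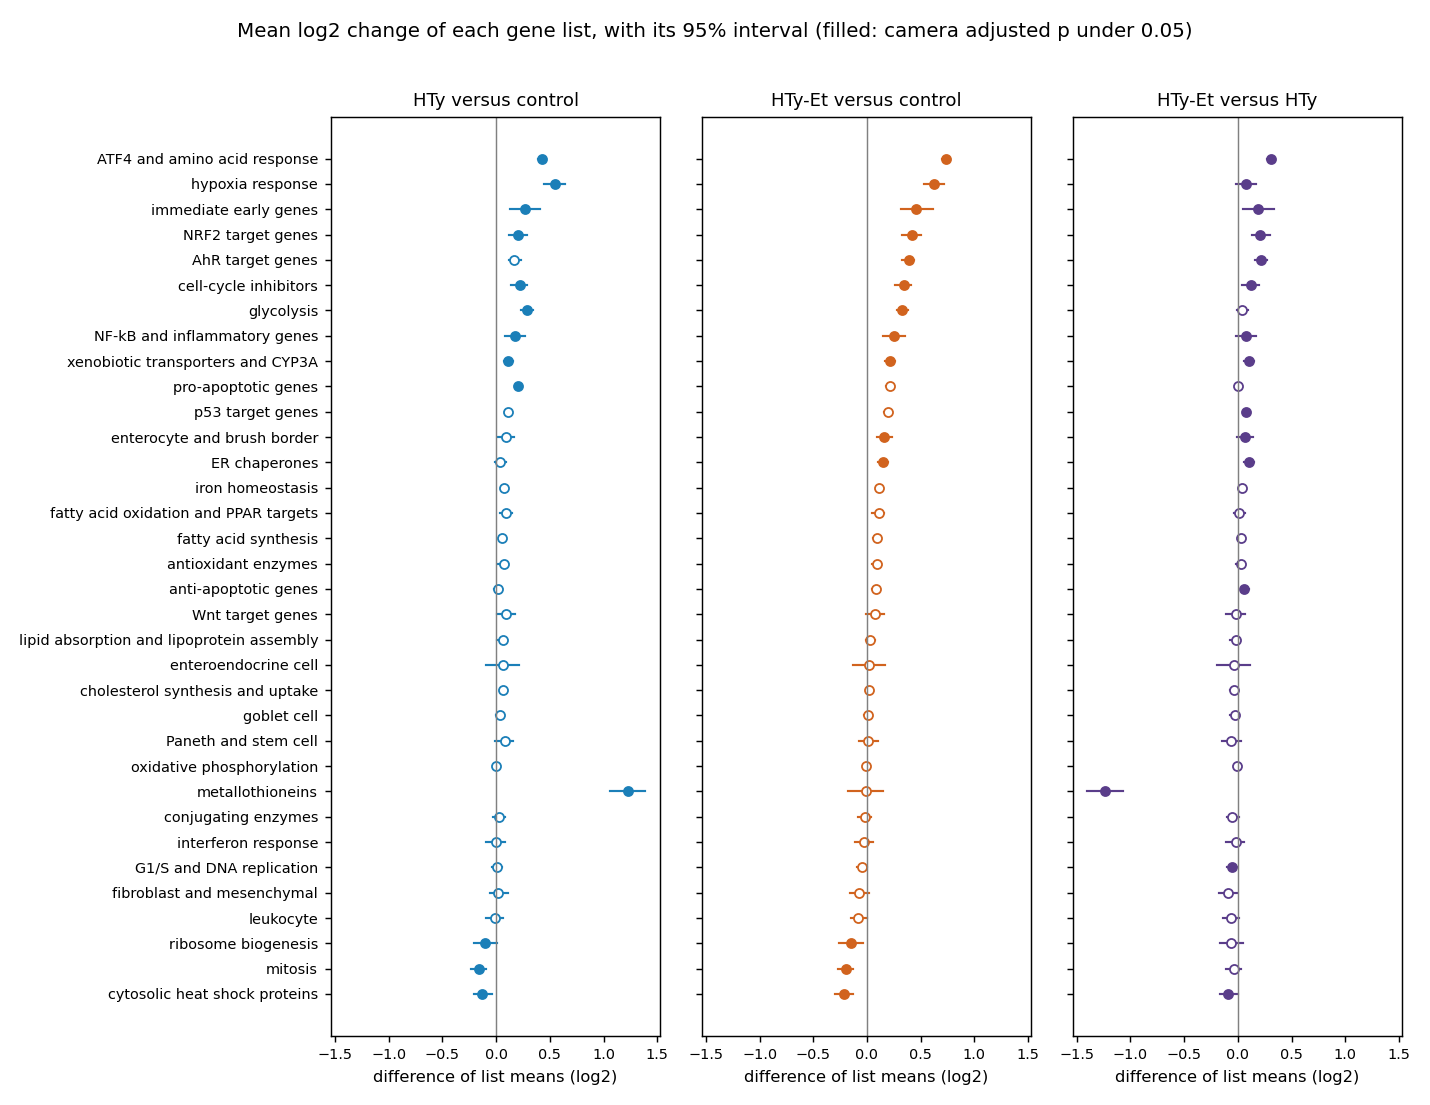
Mean log2 difference of each of the 34 gene lists in the 3 comparisons, with its 95% interval, ordered by the change with HTy-Et on a shared horizontal axis; filled points have a camera adjusted p under 0.05. The ATF4 list stands at 0.74 with HTy-Et and 0.43 with HTy, and the metallothionein list at 1.23 with HTy and -0.01 with HTy-Et.

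Across genes, the responses to the compounds were more alike than in simulations of unchanged groups with shared controls. Those simulations drew each gene independently and so leave out effects that many genes of an array share. They cannot exclude that such an effect in the control arrays made the responses alike. The log2 changes correlated at 0.661, against a mean of 0.501 and a highest value of 0.533 in 100 simulations of unchanged groups with shared controls, and genes are not independent replicates. Their covariance was 0.0153 against 0.00354 in the simulations. Of the 453 genes changed by HTy, 422 (93.2%) were also changed by HTy-Et in the same direction, 324 up and 98 down. The simulations, which leave out real effects, gave at most 0 joint calls in either direction, and independent calls, which leave out the shared controls, would give 33.7 and 5.7, so part of the excess over these values may come from the shared controls. No gene was called in opposite directions. Of the same 453 genes, 353 (77.9%) lay further from the control with HTy-Et. Among the 357 genes higher with HTy-Et than with HTy, 97 were raised by both compounds and 254 passed against the control with HTy-Et alone. Of 31 genes called with HTy alone, 10 differed between the compounds, among them the 6 metallothionein genes named above. Of 2575 genes called with HTy-Et alone, 286 differed between the compounds, so a call with HTy-Et alone does not show a difference from HTy.

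**Figure D3:**
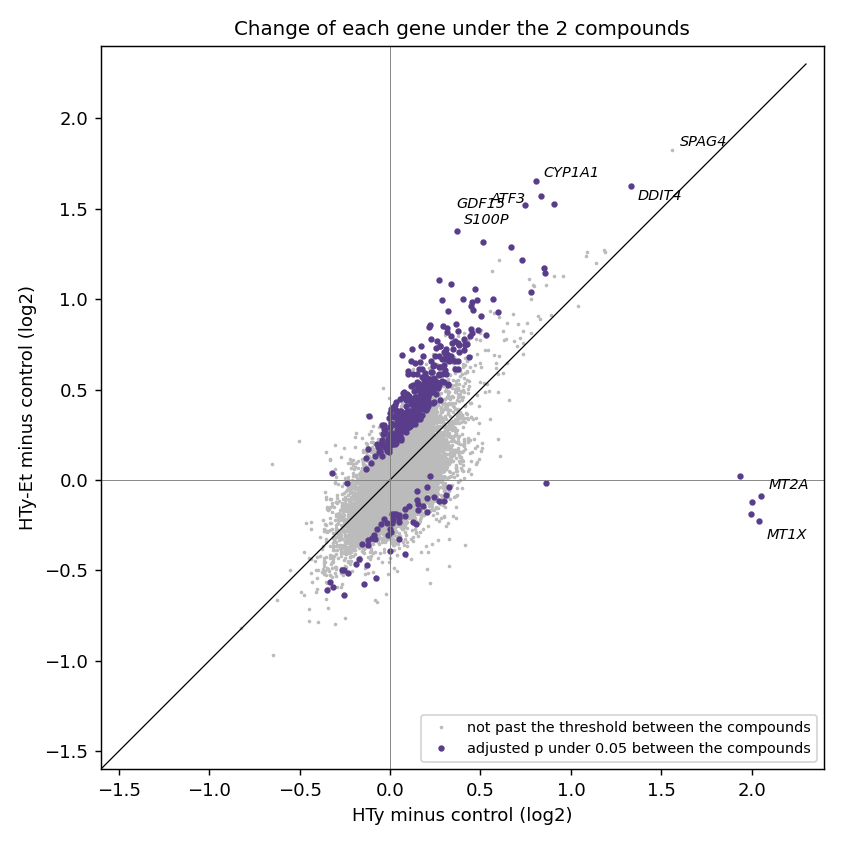
Log2 difference from the control of 19775 genes with HTy on the horizontal axis and HTy-Et on the vertical axis; each point is a gene, purple points differ between the compounds at an adjusted p under 0.05, and the line marks equal change. The correlation is 0.661, and the metallothionein genes lie far to the right near 0 on the vertical axis.

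Some lists share members, so their calls are not independent. For example, SLC7A11 is in the NRF2 and ATF4 lists, NQO1 in the NRF2 and AhR lists, ABCC2 and ABCC3 in the NRF2 and xenobiotic transporter lists, GSR, TXN and TXNRD1 in the NRF2 and antioxidant lists, BAX and FAS in the p53 and pro-apoptotic lists, ATF3 in the ATF4 and immediate early lists, BNIP3 in the hypoxia and pro-apoptotic lists, CDKN1A in the cell-cycle inhibitor and p53 lists, and MYC in the immediate early and Wnt lists. The list median, mean and camera direction differed in sign in several lists, none of them called. With HTy these were the G1/S, anti-apoptotic, enteroendocrine and interferon lists, with HTy-Et the Paneth and stem cell list, and between the compounds the pro-apoptotic, fatty acid oxidation, interferon and enteroendocrine lists. With a correlation estimated for each list, the ATF4 list alone was called, in all 3 comparisons. The directional fry test called 21, 22 and 13 lists for HTy, HTy-Et and their difference, against 13, 14 and 15 with camera, and the mixed fry test called 31, 32 and 25.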

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

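Of the tests below, those of metallothionein cross-hybridisation, of SLC30A1, of the shared control arrays and of the vehicle were chosen only after the result was seen.

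HTy raised metallothionein genes and HTy-Et did not, with a list median of -1.40 for HTy-Et minus HTy. A zinc-type response through MTF1, which would also make the zinc exporter SLC30A1 lower with HTy-Et, stays open, since that gene differed by 0.18 (95% interval -0.04 to 0.40) but its 3 probe sets ranged from -0.12 to 0.43. A glucocorticoid-type response would make its target genes lower with HTy-Et. The mean of 4 measured target genes differed by -0.05 (-0.20 to 0.10), so the predicted fall was not seen. PER1, also named in advance, is not in that mean. Whether these genes respond to glucocorticoids in these cells was not tested, so that response stays open. How many metallothionein transcripts changed stays open, since 0 of the 2 gene-specific probe sets passed and their control intensities, 36.1 and 83.3, are too low to decide whether 1 transcript read by many sets could account for the pattern. Both compounds were given in the same vehicle and medium without serum. The metallothionein list mean differed from the control by 1.23 (1.06 to 1.39) with HTy and by -0.01 (-0.18 to 0.15) with HTy-Et. These values argue against the vehicle or the lack of serum as the cause of the rise in this list. They do not bear on a condition of the HTy dishes alone. The difference between the compounds themselves, which is the biological explanation the design gives, stays open.

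Hypoxia and ATF4 genes were higher under both compounds, which share 3 control arrays, although with an estimated correlation the ATF4 list was called (adjusted p = 0.00516 for HTy and 0.00312 for HTy-Et) and the hypoxia list was not (0.0627 and 0.101). For hypoxia, the list mean of HTy lay 13.8 standard errors from 0, which is beyond the spread within groups. This test restates the rise that prompted it. It cannot detect an offset common to the 3 control arrays, so a chance position of those arrays stays open. A vehicle, a lack of serum or another dish condition shared by treated cells cannot be told apart from the compounds for hypoxia. There the list means differed by 0.08 (-0.02 to 0.17) and, after median centring, by 0.12 (0.01 to 0.24). The labels do not say what the control cells received. For ATF4 the means differed by 0.31 (0.27 to 0.34), which argues against a shared condition as the whole cause of the rise with HTy-Et. A shared condition could still account for the ATF4 rise with HTy and for an equal part of that with HTy-Et. Iron depletion by the catechols, tested through TFRC, could not be decided, with TFRC at 0.08 (0.00 to 0.15) with HTy and 0.06 (-0.01 to 0.14) with HTy-Et. A response to the compounds stays open as the biological explanation.

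More genes passed with HTy-Et (2997) than with HTy (453). A single unusual array is argued against, as the lowest HTy-Et count with 1 array left out was 1887 and the highest HTy count was 204. A larger size of the same changes may account for part of the gap, since 77.9% of the HTy genes lay further from the control in the same direction with HTy-Et. A difference between the compounds stays open as the biological explanation, untested.

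For each of the 3 comparisons, the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 453, 2997 and 419 genes, and 1 of 10 splits gave as many in each comparison, the real split itself. The highest count among the other splits was 0 in each. Those splits mix arrays of both groups, so any real difference adds to their spread and lowers their counts. Their low counts therefore cannot show what chance alone would give.

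Between the compounds, 419 genes differed by a test of the difference itself. Camera, which asks whether a list moves more than other genes, called 15 lists for the same difference. Their medians with HTy-Et minus HTy were 0.26 for ATF4, 0.23 for immediate early genes, 0.19 for NRF2 targets, 0.11 for AhR targets, 0.10 for cell-cycle inhibitors, 0.09 for ER chaperones and 0.07 for xenobiotic transporters. The medians were 0.06 for hypoxia and for anti-apoptotic genes, 0.04 for NF-kB genes, 0.03 for p53 targets and for enterocyte genes, -0.06 for G1/S genes, -0.08 for heat shock genes and -1.40 for metallothioneins. The small medians depend on the scaling of the arrays: median centring moved them by up to 0.05, to 0.11 for hypoxia and -0.01 for G1/S genes, and 0 of the 15 changed sign. Of these lists, ATF4 alone was also called with an estimated correlation.

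Probe sets outside the gene test, which name several genes or are unnamed here, also passed the threshold. There were 43 with HTy against control (18 naming several genes and 25 unnamed), 625 with HTy-Et against control (212 and 413) and 44 between the compounds (20 and 24).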

How the results depend on the processing

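Every alternative set before the data were examined was run. With 1 array left out, the number of changed genes ranged from 114 to 204 for HTy against control, from 1887 to 2882 for HTy-Et against control and from 48 to 286 between the compounds. Fewer arrays leave fewer degrees of freedom, but whether this accounts for the lower counts was not tested. The numbers of lists called ranged from 11 to 16, from 14 to 15 and from 11 to 14, and the correlation of the responses from 0.575 to 0.689.

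Against the 453 genes for HTy, the count was 518 with only the 6 arrays compared, 936 with an intensity trend in eBayes, 284 with median centring, 1009 without dim genes, 786 with a floor of 32 and 56 with a change of at least 1.5-fold. Requiring a fold change can only lower the number of genes. For the others, including the rise without dim genes, the cause was not tested. Against 2997 genes for HTy-Et, the count was 1936 with only the 6 arrays compared, a cause that was not tested, and 203 at 1.5-fold or more. Against 419 between the compounds, it was 86 with the 6 arrays alone, 148 with the replicate number as a block, 783 with the trend, 650 with median centring, 814 without dim genes, 194 with the mean of all probe sets, 669 with the floor of 32 and 23 at 1.5-fold or more. The cause was not tested for the 6 arrays, the trend, the centring, the dim genes, the mean of probe sets, the floor and the block.

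The replicate numbers are shared between the groups but the labels do not say what they mean. Of 9 pairs of arrays with the same number, 3 had residuals correlated above 0.1, with values from -0.031 to 0.248 against -0.266 to 0.154 for other pairs, and 4 of 9 arrays correlated best with their own number. With the number as a block, 316, 2708 and 148 genes and 12, 14 and 12 lists were called. Among the largest changes, the block ended the calls of GTF2H2B, STK24-AS1 and CENPE for HTy and of TXNIP, PLAGL1, ATP6V1C2 and MRPL45P2 between the compounds. Among lists, it ended those of xenobiotic transporters for HTy and of p53 targets, anti-apoptotic genes and NF-kB genes between the compounds. With an estimated correlation, camera called 1 list in each comparison, and fry called 21 lists for HTy and 22 for HTy-Et. The correlation of the responses was 0.732 without dim genes, and the cause was not tested.

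Direction changed for 9 values, and 1 further value went to 0. With the mean of all probe sets of a gene, BCL2 stood at -0.039 with HTy and -0.003 between the compounds, ZEB1 at -0.037 with HTy, and MVK at -0.068, LUM at 0.039 and PTPRC at -0.078 with HTy-Et. Between the compounds under that setting, NDUFS1 stood at -0.004, SLC11A2 at -0.046 and LGR5 at -0.008. None of these 9 had passed the threshold, and the cause was not tested. MRPL45P2 stood at 0 between the compounds with a floor of 32, which lies above its intensities, although it had passed with a floor of 16. Of 72 largest changes, 20 calls ended with 1 array left out and 20 under another setting. Of 42 list calls, 10 ended with 1 array left out and 9 under a setting other than the estimated correlation. Of 3764 values of named genes and lists under other settings, 3388 kept their direction and side of the threshold. Of the rest, 221 no longer passed, 145 newly passed and 10 reversed or, for MRPL45P2, went to 0. With 1 array left out, 2521 of 2910 kept both, 374 no longer passed and 15 newly passed. On arrays, the signal over background limits what can be told for dim probe sets such as the gene-specific metallothionein sets.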

Other observations

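The 8 gene lists here were chosen only after the largest changes had been seen, so their tests are not independent of those genes. All p-values of lists here are from camera and adjusted over 42 lists, these 8 and the 34 fixed before. With an estimated correlation, calls were left only for amino acid transporters with HTy-Et and between the compounds and for circadian clock genes with HTy-Et. Of 18 measured amino acid transporters, 4 rose with HTy (median 0.13, adjusted p = 3.51e-05, and adjusted p = 0.0577 with an estimated correlation) and 11 with HTy-Et (median 0.22, adjusted p = 2.05e-08, and adjusted p = 0.0208). Between the compounds, 3 were higher with HTy-Et (median 0.14, adjusted p = 8.28e-07, and adjusted p = 0.0355). SLC38A2, a neutral amino acid transporter, rose by 0.37 and 0.60, SLC1A4 by 0.42 and 0.67, and the cationic amino acid transporter SLC7A1 by 0.24 and 0.49. The list shares 3 genes with the ATF4 list, SLC3A2, SLC7A11 and SLC7A5. Of 17 cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNAs with amino acids, 1 rose and 1 fell with HTy (median 0.07, adjusted p = 0.42), and 10 rose and 4 fell with HTy-Et (median 0.19, adjusted p = 0.0103, and adjusted p = 0.0934 with an estimated correlation). Between the compounds, 5 were higher with HTy-Et (median 0.11, adjusted p = 0.000115, and adjusted p = 0.0529): CARS1 by 0.31, GARS1 by 0.26, SARS1 by 0.26, AARS1 by 0.25 and YARS1 by 0.19. Of 15 mitochondrial synthetase genes, 0 changed with HTy (median -0.01, adjusted p = 0.245), 1 rose and 2 fell with HTy-Et (median -0.04, adjusted p = 0.19) and 0 differed between the compounds (median -0.02, adjusted p = 0.482).

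Of 14 circadian clock genes, 3 rose with HTy (median 0.13, adjusted p = 0.000948, and adjusted p = 0.0577 with an estimated correlation) and 8 with HTy-Et (median 0.22, adjusted p = 4.37e-06, and adjusted p = 0.0272). Between the compounds 1 was higher, NR1D2 (median 0.15, adjusted p = 0.000853, and adjusted p = 0.0542). CIART, a clock repressor, rose by 0.59 and 0.62 and NFIL3 by 0.50 and 0.83. BHLHE40 is in this list and in the hypoxia list. Of 20 autophagy and lysosome genes, 1 rose with HTy (median 0.07, adjusted p = 0.0107, and adjusted p = 0.141 with an estimated correlation), 9 rose and 1 fell with HTy-Et (median 0.13, adjusted p = 1.87e-05, and adjusted p = 0.06), and 2 were higher with HTy-Et than HTy (median 0.06, adjusted p = 0.000115, and adjusted p = 0.0542). SQSTM1, a receptor that brings cargo to autophagy, rose by 0.29 and 0.59. Of 14 secretory genes typical of liver, 0 changed with HTy (median -0.03, adjusted p = 0.279), 5 fell with HTy-Et (median -0.09, adjusted p = 0.00613, and adjusted p = 0.148 with an estimated correlation) and 1 was lower with HTy-Et than HTy (median -0.16, adjusted p = 0.00308, and adjusted p = 0.12). They were the fibrinogen genes FGG at -0.59, FGA at -0.57 and FGB at -0.52, with APOH at -0.51 and TTR at -0.40. Of 11 YAP/TAZ targets, 0 changed with HTy (median 0.11, adjusted p = 0.973), 4 rose with HTy-Et (median 0.06, adjusted p = 0.12), and 2 were higher between the compounds, ANKRD1 and CRIM1 (median 0.12, adjusted p = 0.00253, and adjusted p = 0.12). Of 9 histone genes, 0 changed with HTy (median -0.10, adjusted p = 0.00682, and adjusted p = 0.245 with an estimated correlation), 1 fell with HTy-Et (median -0.13, adjusted p = 0.00657, and adjusted p = 0.204), and 0 differed between the compounds (median -0.03, adjusted p = 0.321).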
